A study of Mus musculus with 6 samples.

How the data were processed

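RNA from the hearts of BALB/c mice was compared between a control group and a group exposed to chronic intermittent hypoxia (CIH), with 3 arrays per group. Per the labels' protocols, RNA was immunoprecipitated with an antibody against N6-methyladenosine (m6A), and the precipitated RNA (IP) and the RNA left in the supernatant were each digested with RNase R, an exonuclease that degrades linear RNA. An equal amount of spike-in RNA was then added to both, and the IP RNA was labelled with Cy5 and the supernatant RNA with Cy3, with no dye swap. The labels' extraction protocol names a blood RNA kit with globin removal although the tissue is given as heart, so the extraction of these samples is uncertain. The labels number the samples 1 to 3 in each group as replicates and do not say that they came from separate animals, so the p-values measure the spread between these samples, which may be technical.

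Each deposited file is the scanner output of 1 array. Per the file headers, images were processed with Agilent Feature Extraction 11.0.1.1, and its processed signals are intensity values on a linear scale after background subtraction and a linear and lowess dye normalization within the array. Per the file headers, the deposited log ratio is the log10 of Cy5 over Cy3, which is IP over supernatant. These steps set the overall dye balance of each array, so the level of the log ratio is relative to the other probes of that array. The log ratio was recomputed on the log2 scale from the processed signals. The array holds 14236 circRNA probes of 1 spot each, 102 spike-in probes of 3 spots, 50 mRNA probes of 10 spots and 15 negative probes. Spots with an outlier mark in either channel were left out (35 circRNA spots over the 6 arrays), the spots of a probe were averaged, and no circRNA spot was saturated.

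For each circRNA the log2 ratio was centred on the array's median over circRNA probes. The log2 IP signal, the log2 supernatant signal and the log2 of their sum (total signal, meant as a measure of abundance irrespective of m6A) were each set against the array's 75th percentile. The fractions were labelled separately and their channels balanced by the dye normalization. The sum therefore weighs them arbitrarily and can still depend on m6A. CircRNAs were tested when well above background on at least 3 of the 6 arrays, in either channel for the log ratio and the total signal and in the tested channel for the others. Groups were compared with limma 3.58.1 in R 4.3.3 (linear model, empirical Bayes with an intensity trend, two-sided, no covariate), and Benjamini-Hochberg adjusted p under 0.05 was the threshold. The array-wide IP share is the median over tested circRNAs of IP signal as a percentage of IP plus supernatant signal, after scaling each channel to 47 spike-in probes well above background on all arrays, and was compared with an exact permutation test, whose smallest two-sided p with 3 against 3 is 0.1. The number of arrays limits the precision of these tests.

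The tests were tried on simulated data with 200 changed circRNAs per measure and each circRNA's spread within the real groups. The noise was normal, independent between circRNAs and equal on all 6 arrays. It therefore lacks outlying arrays and noise shared between circRNAs, and the recovery on the real arrays may differ. Of 50 circRNAs set to change 2-fold, 5 were recovered in the log ratio, 17 in the IP signal, 11 in the supernatant signal and 23 in the total signal. Of 50 set to change 4-fold, the same tests recovered 22, 41, 40 and 43. They made 7, 7, 6 and 13 false calls respectively.

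The files name circRNAs by the vendor's probe ID and do not pair them with host genes or coordinates, and 0 of these IDs matched the gene tables used here. The 14 host gene lists written before the data were examined (among them sarcomere, calcium handling, hypoxia response and cell type markers) were therefore not tested, and no circRNA of a named host is reported. The rule for named circRNAs, also written before the data were examined, took for the log ratio and the total signal the 8 largest rises and falls past the threshold, filled up by smallest unadjusted p, among circRNAs well above background on all 6 arrays (in both channels for the log ratio), and the 5 highest and 5 lowest control log ratios. Because the IDs have no gene names, 2 per direction are printed. The circRNAs named for the IP signal and the mRNA probes were chosen after their values were seen. Of the 50 mRNA probes, 46 were named through their RefSeq accession in a table of assembly GRCm38.p6, used for names only.

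Alternatives covered the background correction (normexp with offset 50 on median signals, since the files hold no mean signal), normalization, filters, spike-in scaling, array weights, slide, moderation, thresholds, a replicate block and leaving out each array. The median signals precede the dye normalization, so the normexp setting drops that step as well as changing the background correction. Its added offset by itself shrinks the log changes of dim probes. These parts of normexp were not tried separately. Added after seeing the data were signals without dye normalization, outlier spots kept, and the arrays of 1 slide alone. The headers place the 3 control arrays and CIH 1 on slide 1 and CIH 2 and CIH 3 on slide 2. Slide 2 thus holds no control array, so with slide as a block the estimated change is that of CIH 1 against the 3 control arrays.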

Results

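The series measured m6A, a methyl mark on adenosine, on circular RNAs (circRNAs) in the hearts of mice exposed to CIH, a model of obstructive sleep apnea. In the exposed group O2 was lowered to 6% for 60 s and returned to 21% for 60 s in cycles of 2 min, 30 times per h and 8 h per day for 8 weeks. The array reads IP and supernatant RNA of each sample in separate dyes, for 3 control and 3 CIH samples. Of 14236 circRNA probes, between 4521 (CIH 1) and 7224 (CIH 3) were well above background in the IP channel, and between 3862 (control 3) and 6235 (control 2) in the supernatant channel. The median spot was 1.69 to 2.47 times its local background in the IP channel and 2.18 to 3.36 times in the supernatant channel. In neither channel of any array were 5454 circRNAs well above background, and 3096 were so in both channels of all 6 arrays with no outlier mark.

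The first comparison asked whether m6A on circRNAs differed between CIH and control hearts. No circRNA passed the threshold in the IP over supernatant log2 ratio. The limma test gave 0 higher and 0 lower of 6915 tested, with a smallest adjusted p of 0.953. At an unadjusted p under 0.05 there were 79 higher and 96 lower, fewer than the 345.75 that chance gives, and the per-probe test without moderation also gave 0 after adjustment. Over the 3096 circRNAs measured throughout, the group means correlated across circRNAs with r = 0.939, and the median absolute difference was 0.13 on the log2 scale, where circRNAs are not independent replicates.

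Among the circRNAs well above background in both channels of all 6 arrays, the smallest unadjusted p for a higher ratio in CIH belonged to ASCRP4012517, whose log2 ratio was -0.75 ± 0.24 in control and 0.27 ± 0.25 in CIH (SD, n = 3; limma adjusted p = 0.999). The log2 ratio of ASCRP4006128 was -0.02 ± 0.25 in control and 0.71 ± 0.16 in CIH. Among lower ratios, ASCRP4000953 had 0.86 ± 0.37 in control and 0.16 ± 0.11 in CIH, and ASCRP4004967 had 0.01 ± 0.26 and -0.76 ± 0.24. None of these 4 passed the threshold, and with normexp their log2 changes were 0.16, 0.27, -0.11 and -0.19 in place of 1.02, 0.72, -0.70 and -0.77.

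The ratios were skewed to low values in both groups. Among those 3096 circRNAs, the highest mean log2 ratio over the control arrays was 1.34 ± 0.73 for ASCRP4002539 (SD, n = 3), with 0.82 ± 0.74 in CIH. The next was ASCRP4000828, with 0.73, 0.67 and 2.61 on control 1, 2 and 3 and 0.72 ± 0.60 in CIH. The lowest were -5.01 ± 0.80 for ASCRP4009097 and -4.56 ± 0.85 for ASCRP4006634, with -4.41 ± 0.30 and -4.07 ± 0.28 in CIH. With no dye swap, a single ratio also carries the probe's own dye response, which cancels between groups. On 5 arrays, all but control 1, 165 of 3096 circRNAs lay below -1 throughout, and 0 lay above 1 throughout. The median of these 165 was -2.76 over control 2 and control 3 and -2.25 over CIH, but -0.25 on control 1, where 33 of them also lay below -1. ASCRP4009097 and ASCRP4006634 were among these, with -4.38 and -3.77 on control 1.

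Control 1 stood apart from the other arrays in its ratios. The SD of its log2 ratios was 0.35, against at least 0.68 on each of the other arrays. Its ratios correlated with those of the other arrays at r = 0.32 to 0.46 across circRNAs, while the other 5 arrays correlated with each other at 0.80 to 0.94. The supernatant profile of control 1 correlated at 0.979 with the mean IP profile of the other arrays and at 0.929 with their mean supernatant profile. Its IP profile correlated at 0.992 with the other IP profiles. Without control 1, the log ratio test still gave 0 circRNAs past the threshold, with 201 higher and 203 lower at an unadjusted p under 0.05.

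**Figure D1:**
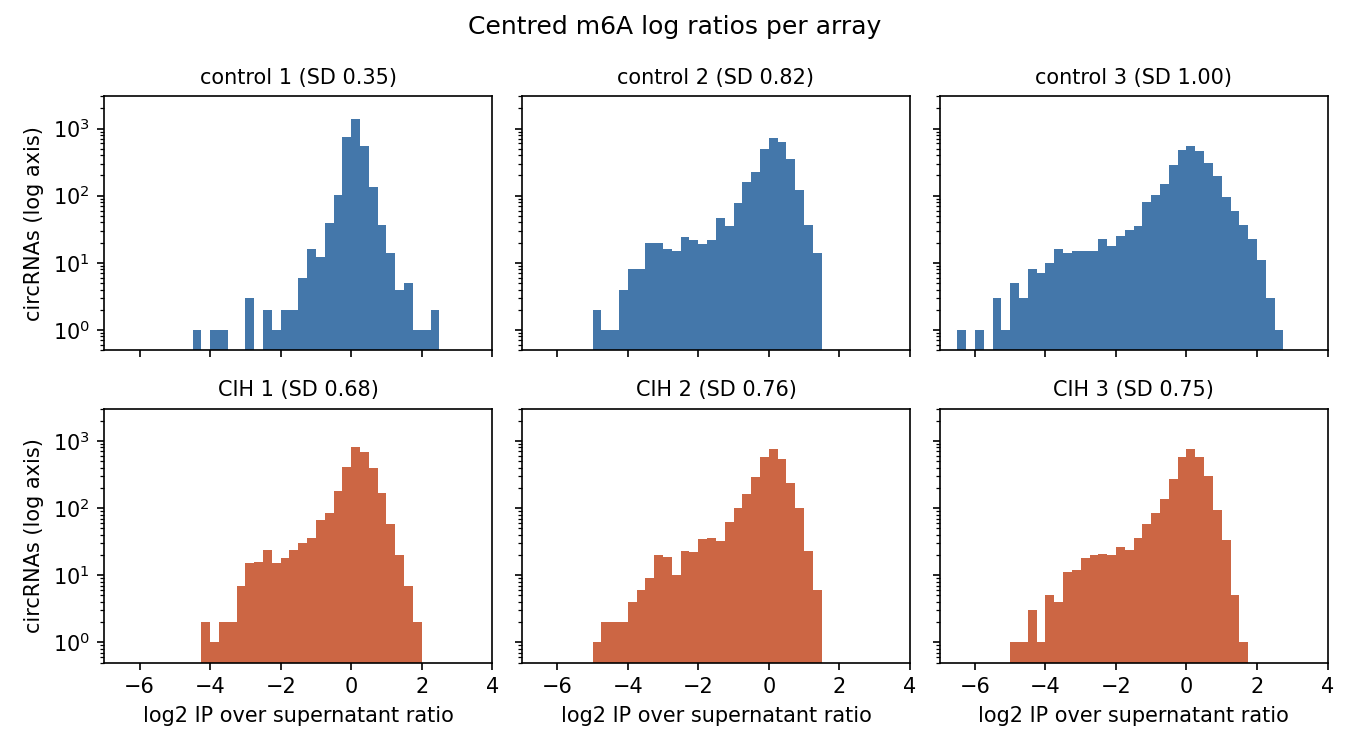
Number of circRNAs (log axis) by centred log2 IP over supernatant ratio, for the 3096 circRNAs well above background in both channels of all 6 arrays, 1 panel per array. The SD is 0.35 on control 1 and at least 0.68 on each of the other arrays, which share a tail of low ratios.

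The second comparison asked whether more or less of each circRNA was immunoprecipitated. In the IP signal, 88 circRNAs were higher in CIH and 0 lower, of 6274 tested with limma. At an unadjusted p under 0.05, 457 were higher and 177 lower, where chance gives 313.7, but this balance depended on the scaling and the arrays. It was 268 and 1304 with median scaling, 491 and 564 with array weights, 463 and 555 without control 2 and 432 and 626 without control 3. The rises of the 88 ran from 1.79-fold to 6.37-fold with a median of 2.62-fold, a log2 rise of 1.39 that was 0.38 with normexp. The offset of normexp shrinks the changes of dim circRNAs, so this drop does not measure background alone. The groups did not overlap for any of the 88, which were picked on these same values, while chance gives no overlap, in either direction, for 10% of circRNAs. The largest rises among those well above background on all arrays were picked after the result was seen, which favours large values. The log2 IP signal of ASCRP4009692 rose from 3.54 ± 0.38 to 5.84 ± 0.88 (SD, n = 3; 4.91-fold, log2 change 2.30 with SE 0.35, limma adjusted p = 0.0136). That of ASCRP4002727 rose from 0.38 ± 0.74 to 2.37 ± 0.89 (3.99-fold, log2 change 2.00 with SE 0.41, limma adjusted p = 0.0375). Neither passed without CIH 1 (limma adjusted p = 0.0593 and 0.207), without CIH 2 (0.123 and 0.257) or with slide as a block (0.110 and 0.0571, at log2 changes of 1.75 and 2.67). With single arrays left out, the log2 change of ASCRP4009692 ran from 1.79 without CIH 3 to 2.57 without CIH 1. That of ASCRP4002727 ran from 1.63 without control 3 to 2.50 without CIH 3. ASCRP4009692 also did not pass with normexp (0.0644, log2 change 2.11), and ASCRP4002727 did not pass without control 1 (0.121), without control 3 (0.0527), with quantile normalization (0.108) or among circRNAs well above background on all arrays (0.0663), and its log2 change was 0.87 with normexp. Without moderation neither passed.

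The same 88 circRNAs had a higher mean supernatant signal in CIH in 87 cases, with a median of 2.37-fold, although 0 of the 80 tested there passed the threshold. The log2 ratio of IP over supernatant was higher in CIH for 48 and lower for 40, with a median change of 0.05. Without control 1, the supernatant mean was higher for 82 of the 88, its median log2 change was 0.62 in place of 1.24, and the median change of the log2 ratio was 0.79. Of the 88, 47 were well above background in the IP channel on all 6 arrays and 5 were dim there on all 3 control arrays, where their rise has only a lower bound.

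**Figure D2:**
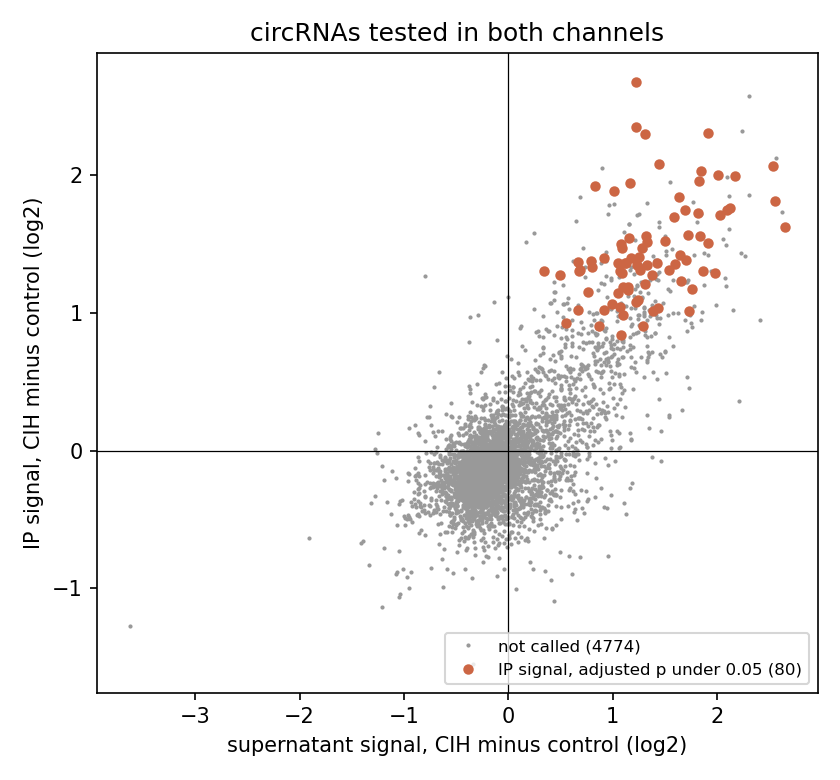
Log2 change (CIH minus control) in the IP signal against that in the supernatant signal for 4854 circRNAs tested in both channels, with 80 circRNAs past the threshold in the IP signal as larger points. All 80 were higher in CIH in the mean supernatant signal too, where the control mean includes control 1. Without control 1, the supernatant mean was higher in CIH for 82 of all 88 circRNAs past the threshold in the IP signal.

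The IP count rested on the moderated test and on single arrays. It was 0 without moderation, 0 without CIH 1, 0 without CIH 2, 35 without control 1 and 184 without control 2, and 6 circRNAs passed with slide as a block. The size of the rise changed less, though the 88 were picked on these same arrays. All 88 stayed higher in CIH, with a median log2 rise of 1.31 without CIH 1 and 1.37 without CIH 2. Since their groups did not overlap, leaving out an array could not reverse any of them. Moderation does not enter the estimate, so the median was 1.39 without it by construction. The median was 0.38 with normexp. It was 1.65 both with slide as a block and on slide 1 alone, which holds the 3 control arrays and CIH 1 as its only CIH array. These are the same estimate and not separate results, since slide 2 holds no control array.

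The third comparison took the supernatant signal, the RNA not bound by the antibody. Of 5425 circRNAs tested with limma, 0 were higher and 0 lower, with 193 higher and 59 lower at an unadjusted p under 0.05 where chance gives 271.25, and 0 without moderation. The unadjusted counts were 130 higher and 365 lower with median scaling, and 297 and 542 without control 3. The smallest adjusted p was 0.686. Without control 1, the count also was 0.

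The fourth comparison took the total signal, meant as a measure of abundance. It depends on the balance of the channels, and control 1 is included. On control 1, whose supernatant profile was close to the IP profiles, the log2 total signal of the Hspb7 mRNA probe was 1.77. It was 3.28 to 4.18 on the other arrays. Of 6915 circRNAs, 0 were higher and 0 lower in limma, with 549 higher and 122 lower at an unadjusted p under 0.05 where chance gives 345.75, and 0 without moderation. The unadjusted counts were 425 higher and 488 lower with median scaling, and 687 and 775 without control 3. Among circRNAs well above background in a channel on all 6 arrays, the smallest p for a higher signal were those of ASCRP4009976 and ASCRP4006538. The log2 total signal of ASCRP4009976 was 0.58 ± 0.46 in control and 2.06 ± 0.12 in CIH (SD, n = 3; limma adjusted p = 0.228), and that of ASCRP4006538 was -0.02 ± 0.04 and 1.07 ± 0.17. Both passed in the IP signal alone, by 2.86-fold and 2.57-fold with a limma adjusted p of 0.0136 each. On the lower side, ASCRP4002183 had 3.40 ± 0.19 in control and 2.53 ± 0.20 in CIH, and ASCRP4000264 had 0.98 ± 0.14 and -0.01 ± 0.19, neither of which passed. With normexp the log2 changes of these 4 were 0.59, 0.32, -0.55 and -0.27 in place of 1.48, 1.08, -0.88 and -0.99, and ASCRP4009976 passed there (adjusted p = 0.00113), without control 2 (0.0164), with median scaling (0.0315) and without the filter on dim probes (0.0115). ASCRP4006538 passed without control 2 (0.0416) and without the filter (0.0319), ASCRP4002183 without the filter (0.0311) and with median scaling (0.0453), and ASCRP4000264 with median scaling (0.0352). Without control 2, 130 circRNAs were higher and 3 lower in the total signal. Without control 1, the count was 0 as with all arrays.

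The array also carries 50 mRNA probes, of which 27 were tested in the total signal. The probe of H2-Q7, a gene of the MHC class I family, was higher on each CIH array than on each control array, and the mRNA probes were tested after their values were seen. Its log2 total signal rose from 0.62 ± 0.14 to 2.35 ± 0.30 (SD, n = 3; 3.33-fold, log2 change 1.73 with SE 0.21; limma adjusted p = 0.000252 over the mRNA probes alone and 0.0649 over all circRNA and mRNA probes), and its log2 change was 0.71 with normexp. Its log2 IP signal rose from 0.33 ± 0.49 to 2.20 ± 0.65 (3.67-fold, log2 change 1.88 with SE 0.32; limma adjusted p = 0.00153 over the mRNA probes alone and 0.0193 over all), but it did not pass over the mRNA probes without moderation (adjusted p = 0.142), and its log2 change was 0.93 with normexp. In the supernatant signal it had 0.75 ± 0.71 in control and 2.42 ± 0.41 in CIH, with a limma adjusted p of 0.0547 over the mRNA probes alone and 0.684 over all, and of 0.0231 and 0.560 without control 1. Over the mRNA probes alone it was 0.904 with slide as a block, 0.161 with spike-in scaling and 0.145 with normexp, where the log2 change was 0.49 in place of 1.67. Over the alternatives, the supernatant signal of this probe passed in 6 and did not pass in 15. Class I genes are near-identical in sequence, so the probe may read more than H2-Q7. The only other mRNA probe past the threshold over the mRNA probes alone, an unnamed one, was 2.08-fold higher in the IP signal (limma adjusted p = 0.0176), and 0.107 without control 1.

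The probes of Hspb7, Apoe and Pex11a, picked after their values were seen, passed in none of the measures. Hspb7, which encodes a small heat shock protein of heart and skeletal muscle, had a log2 IP signal of 1.22 ± 0.47 in control and 1.21 ± 0.27 in CIH (SD, n = 3). Its log2 IP over supernatant ratio was -3.57 on control 2, -3.68 on control 3 and -3.13 ± 0.21 over CIH, but -0.46 on control 1. Apoe, an apolipoprotein, had a log2 total signal of 3.33 ± 0.13 in control and 3.35 ± 0.11 in CIH. Pex11a, a peroxisomal membrane protein gene, had a log2 ratio of 1.05 ± 0.23 in control and 1.19 ± 0.40 in CIH. Over the mRNA probes, 0 passed in the log ratio.

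**Figure D3:**
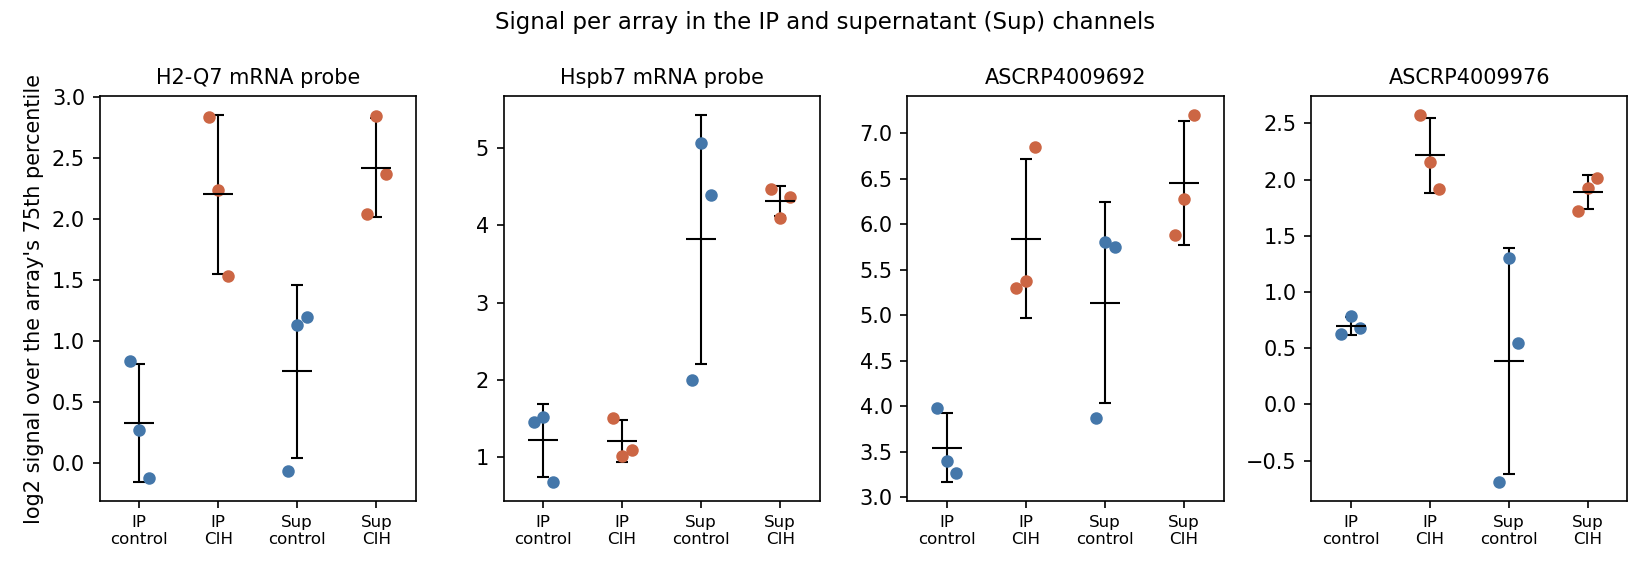
Log2 signal relative to the array's 75th percentile in the IP and supernatant (Sup) channels for the H2-Q7 and Hspb7 mRNA probes and circRNAs ASCRP4009692 and ASCRP4009976. Points are arrays and bars are the mean with its SD (n = 3); in the IP channel the CIH arrays lie above the control arrays for all but Hspb7, and the vertical axis differs between panels.

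The last comparison was the share of circRNA signal in the IP fraction over the whole array. The median IP share was 51.9% ± 1.68 in control and 50.8% ± 1.45 in CIH (SD, n = 3), a difference of -1.08 percentage points (exact two-sided permutation p = 0.5). In the main setting the difference was smaller than the spread between samples of a group. The dye normalization balances the channels of an array before this scaling, so it may have removed an array-wide difference. The share was 50.4% even on control 1. Without dye normalization the share was 47.5% ± 2.13 in control and 46.0% ± 1.26 in CIH (difference -1.49, exact permutation p = 0.4). With normexp, which also lacks the dye normalization and adds an offset, the difference was -3.76, larger than the SDs of 3.26 and 2.44 (exact permutation p = 0.3).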

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

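Signals without dye normalization, outlier spots kept and slide 1 alone were tried after the data were seen. The log ratio count stayed at 0 in 21 of 22 alternatives and was 168 with an unadjusted p and a fold threshold. The IP count of 88 moved by over 1.5 times in 15 of 21. It was 36 with normexp, 40 with quantile normalization, 47 with median scaling and 31 among circRNAs well above background on all arrays. It was 289 without a filter on dim probes, 188 with array weights and 539 with an unadjusted p and a fold threshold. With slide as a block it was 6, without moderation 0, and without single replicates 0 to 184. Scaling to spike-in probes gave 122, all higher in CIH. The supernatant count was 1 with normexp and 241 with an unadjusted p and a fold threshold, and 0 in the other 19 alternatives. The total count was 29 with normexp, 107 without the filter, 78 with median scaling (60 higher, 18 lower), 628 with an unadjusted p and a fold threshold, and 0 to 133 without single replicates. Lower circRNAs passed without the filter (9), with array weights (1), median scaling (4) or an unadjusted p and a fold threshold (109), and without control 2 (21) or CIH 3 (1), all in the IP signal. The cause of these moves was not tested.

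The replicate numbers did not clearly pair the samples. The correlations of same-numbered deviations were 0.24, 0.10 and -0.03 in the log ratio and -0.03, 0.02 and -0.24 in the IP signal. They were 0.12, 0.27 and -0.01 in the supernatant signal and -0.06, 0.14 and -0.20 in the total signal. Not every sample correlated best with its own number, though numbers 1 and 2 did in the supernatant signal. Number 1 did so in the log ratio and number 2 in the total signal. With 3 samples per group this cannot settle pairing. With a replicate block the counts were 0 in the log ratio, 0 in the IP signal, 0 in the supernatant signal and 0 in the total signal. None of the 88 IP calls passed there, ASCRP4009692 and ASCRP4002727 included. The median log2 rise of the 88 was 1.39 as in the main setting, since a block balanced over the groups leaves the estimate as it is. For the same reason the IP share difference with this block was again -1.08 percentage points. That difference kept its sign in all 12 alternatives, from -3.76 with normexp to -0.18 as deposited; with single replicates left out it ran from -1.84 to -0.18. The total signal of the H2-Q7 probe kept its direction and its call over the mRNA probes in all 21 alternatives, with 0.71 under normexp as the smallest log2 change. The host gene list tests and their alternatives were not run, since the circRNA IDs carry no host gene, and leaving out saturated probes removed none.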

Other observations

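Chosen only after the result, or values that foretold it, had been seen were the tests of control 1 (mixture and its low ratios, dim signal, dye normalization), of carry-over, of m6A with unchanged abundance, of the H2-Q7 probe, of the vendor control probe and of the splits for the log ratio, IP and total signals. A vendor control circRNA probe, AS_circRNA_control3000013, was lower in CIH by -0.87 in the log2 total signal (limma adjusted p = 0.00846 over the vendor control probes).

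The narrow log ratios of control 1 were not explained by dim signal, since the SD among the brightest circRNAs was 0.42 on control 1 and at least 0.81 on each other array. Nor did they come from the dye normalization, since without it the SD was 0.36 against at least 0.69. A mixture of the mean IP and supernatant profiles of the other arrays rebuilt the supernatant channel of control 1 best with a weight of 0.93 on the IP profile, against 0 to 0.08 on the other arrays, so a candidate explanation is that IP RNA, or RNA with the profile of IP RNA, was labelled in the supernatant channel there. It does not cover every circRNA: of the 165 low on the other arrays, 33 lay below -1 on control 1 and the mixture puts 24 there, 16 of them the same, and for ASCRP4002183 it gives -0.55 where -3.52 was measured. Whether the sample was also a heart with another m6A pattern stays open, and no biological explanation was tested.

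The rise of circRNAs in the IP signal was set against slide, carry-over and m6A. Slide alone is argued against: circRNAs picked as higher on the 2 CIH arrays of slide 2 than on 2 control arrays were also higher on CIH 1 than on the held-out control array of slide 1, by a median beyond all tested circRNAs of 1.36 to 1.72 (log2) in 3 rotations, though all rest on CIH 1 as the only CIH array there. Supernatant RNA carried into the IP channel was fitted as a mixture on the circRNAs not called, with weights of 0.06 to 0.12 on the CIH arrays. At these weights it left a median rise of 1.31 of 1.49 and did not account for the whole rise. Leaving the called circRNAs out of the fit can bias the weights low, so carry-over stays open. The called circRNAs had low log2 ratios on control 2 and control 3 (median -1.36, against 0.17), as carry-over needs, though picking low control IP signal also lowers them. Higher m6A with unchanged abundance would not raise the supernatant signal, whose change without control 1 had a lower quartile of 0.31. However, 0 of the 80 tested there passed the threshold. Both channels were read on the same single spot per circRNA, and the 88 were picked on the IP signal of these arrays. Noise shared by the channels of a spot would raise both, so these values cannot decide it. Higher m6A, higher abundance or both stay open as hypotheses. Of 10 splits of the 6 arrays, 1 (the real one) gave 88 circRNAs or more and the highest other gave 0, and with 10 splits the share cannot be under 0.05.

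The H2-Q7 probe was not one of many mRNA probes that moved. The other 26 mRNA probes tested in the total signal had a median log2 change of -0.20, with an upper quartile of 0.04. Their changes ran from -0.61 to 1.26, the highest being that of Gsta4, which was 0.55 without control 1. The unnamed probe past the threshold in the IP signal changed by 1.01, and by 0.86 without control 1, so H2-Q7 was not alone. The lack of a general rise argues against more linear RNA left on the CIH arrays as a whole. On slide 1 alone the log2 change of the H2-Q7 probe was 1.85. However, slide 1 holds 1 CIH array, which also helped to pick the probe, so slide stays open. A higher level of H2-Q7 or of other class I transcripts in the CIH hearts, or more immune cells there, may account for it, and neither these nor sequence shared among class I genes was tested. In the log ratio, the supernatant signal and the total signal the real split gave 0 calls, a count that all 10 splits reach whatever the data, so these splits decide nothing; the highest other gave 0.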
